A study of Mus musculus with 8 samples.

How the data were processed

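The series holds RNA-seq of NMuMG cells, a normal mouse mammary gland epithelial line, treated with the vehicle DMSO or with BRM014 for 6 h or 30 h. The dose of BRM014 was not given in the sources used here. Each of the 4 groups has 2 libraries, which the labels call biological replicates, without saying whether they came from separate passages or days. Per the labels, total RNA was extracted with a column kit, made into stranded total RNA libraries and sequenced as single reads of 50 bases on a NovaSeq 6000. The deposited values are raw counts per gene with Entrez IDs and symbols. The submitters' processing notes name the mouse genome build mm9, Subread, SAMtools 0.1.19 and featureCounts, without their order. The other versions, the annotation and the strand setting were not given. The counts were whole numbers with different totals per library, and no normalization was seen in them.

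The libraries held 21035954 and 19967836 counts (DMSO 6 h), 18065689 and 22797541 (DMSO 30 h), 19358831 and 23332170 (BRM014 6 h) and 17859693 and 29955366 (BRM014 30 h). Between 13286 and 13922 of 21240 genes had a count in a library, and the 10 genes with most counts took 4.43% to 5.19% of a library. Replicates correlated with r = 0.990 to 0.994 on the log2 CPM scale. The spread between replicates exceeded counting noise (chi-square per degree of freedom 6.67 to 18.2), and the biological coefficient of variation was 9.30%.

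Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (11835 of 21240, 55.7%), libraries were scaled with TMM (factors 0.935 to 1.05), and 1 quasi-likelihood fit held the means of the 4 groups for all 8 libraries, with 4 residual degrees of freedom. Tests were 2-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison, with 0.05 as the threshold. Every adjusted p in the report is a Benjamini-Hochberg p from edgeR, limma or DESeq2, and list tests were adjusted over the sets of tests given below. The closing section also gives an exact sign test and permutation p-values, which are not adjusted. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F value. The comparisons were BRM014 against DMSO at 6 h and at 30 h, the difference between these effects, and 30 h against 6 h in DMSO. BRM014 at 30 h against 6 h was added after the data were seen. The 6 h and 30 h comparisons share no library. Overlaps of called genes are given with odds ratios from Fisher's exact test and with the number that independent lists would share. Genes are not independent replicates, so the test's p was not used, and the intervals of the odds ratios do not measure the spread between libraries. Principal components were computed on log2 CPM with a prior count of 2.

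Gene lists were written before the data were examined, from general knowledge: 24 lists of genes of the complexes, mammary cell identities, pathways and metabolism named in the report, and 5 lists of markers of other cell types, with 664 entries in all. Of these, 661 were found in the table, and Srcap, Hist1h2ad and Col6a3 were not. Some genes belong to more than 1 list. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at its preset correlation of 0.01, adjusted over the 48 tests of the 6 h and 30 h comparisons. The tests were repeated with an estimated correlation and with fry. The 5 marker lists had fewer than 5 tested members each and were not tested as groups. List tests for the other comparisons were added after the data were seen, and each of them was adjusted over its own 24 tests.

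The genes named in the report follow a rule written before the data were examined. It took Smarca4 and Smarca2, and at each time the 6 highest and 6 lowest log2 fold changes among genes with adjusted p below 0.05, a mean log2 CPM of at least 2 and both treated libraries beyond both control libraries. Symbols of the form Gm plus digits, ending in Rik, or starting with LOC or a small RNA prefix were left out. So were symbols that start with BC, AK or a letter from A to F followed directly by digits. C3, F3 and any other gene whose symbol starts this way were thereby removed from this part of the rule. It also took the 3 members with the smallest p of each list that passed (at most 8 lists per time), and the 4 highest and 4 lowest genes for the difference and for time in DMSO. Other genes are marked as named after their values were seen. Some genes that the rule names are not reported here. Where a group held 1 to 3 counts, the ratio is given with its exact 95% interval, which covers counting error and not the spread between libraries.

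The alternatives chosen before the data were examined were RLE factors, library totals, and factors set by the ribosomal protein and oxidative phosphorylation lists (housekeeping scaling) in place of TMM. Others were no filter on low counts, a stricter filter (1 CPM in at least 4 libraries), DESeq2 1.42.0, limma-voom, a fold threshold of 2, counts thinned to the smallest library, only the 4 libraries of a comparison, the replicate number as a block, and leaving out each library in turn. The tests were checked on simulated data, made from the means and dispersions of the libraries, with 200 changed genes among 11835. At 6 h, true changes of 1.5-fold, 2-fold and 4-fold were recovered in 52.2%, 80.6% and 95.5% of genes, with 7.88% of calls false. At 30 h these values were 52.2%, 82.1%, 95.5% and 9.47%, and for the difference between the effects 22.4%, 70.2%, 84.9% and 8.53%. A raised list was found in 10 of 10 simulations, with 4 of 230 other lists called. Genes were simulated as independent, so this check could not show list calls that come from correlation between genes.

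The placement of genes on chromosomes came from an annotation of the mouse reference GRCm38, matched by Entrez ID (11802 of the tested genes, with 33 not placed). It was used only for gene order and overlapping spans. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for these counts and the plots. Reads, other assays and the chromatin of these genes were not analysed here.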

Results

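RNA from NMuMG mouse mammary epithelial cells was compared after 6 h and 30 h with BRM014, an inhibitor of the ATPase activity of the SWI/SNF catalytic subunits SMARCA4 and SMARCA2, or with the vehicle DMSO. Each of the 4 groups had 2 libraries, so every gene value below is a comparison of n = 2 with n = 2 libraries, given as a log2 fold change ± its standard error from the edgeR fit. The first principal component, with 51.3% of the variance, separated BRM014 from DMSO, and the next, with 30.8%, separated 30 h from 6 h. Of 11835 tested genes, 2815 differed between BRM014 and DMSO at 6 h and 4248 at 30 h.

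**Figure D1:**
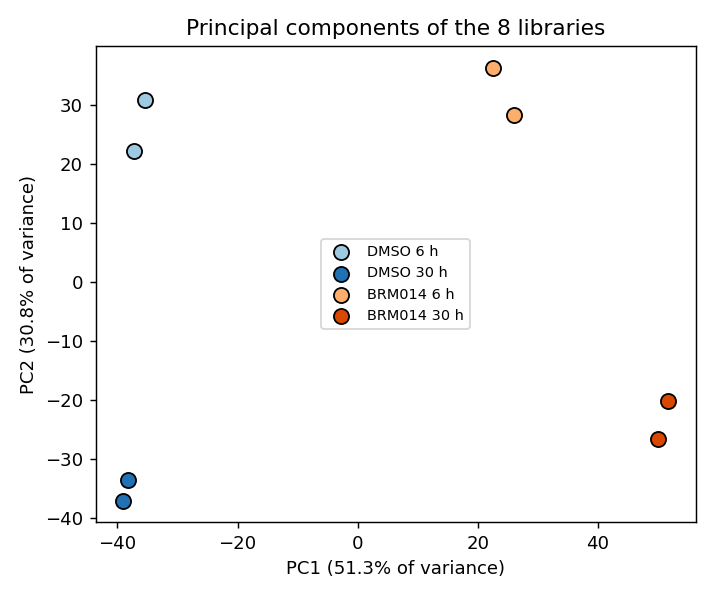
Scores of the 8 libraries on the first 2 principal components of log2 CPM (arbitrary units), coloured by group. The 2 libraries of each group lie next to each other, with BRM014 at positive and DMSO at negative scores on the first component (51.3% of variance).

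The transcripts of the inhibited ATPases did not pass the test at either time. Smarca4 (Entrez 20586) changed by -0.04 ± 0.09 at 6 h (adjusted p = 0.827) and 0.08 ± 0.09 at 30 h (adjusted p = 0.565), from a mean of 460 CPM (counts scaled to a library of 1e6) in DMSO at 6 h. Smarca2 (Entrez 67155) was expressed at 2.98 CPM in DMSO at 6 h and changed by 0.08 ± 0.24 (adjusted p = 0.856) and 0.26 ± 0.21 (adjusted p = 0.347). Of 25 tested SWI/SNF subunit genes, 2 rose, none fell and 23 did not pass at 6 h. At 30 h 5 rose, 3 fell and 17 did not pass. The list did not pass as a group at either time (adjusted p = 0.123 and 0.639), and at 30 h its median (-0.05) and mean (0.06) differed in sign. Named after their values were seen, the accessory subunit genes Bicral (1.30 ± 0.12, then 1.35 ± 0.12) and Bcl7c (0.81 ± 0.15, then 0.51 ± 0.15) rose at both times. At 30 h Dpf1 (0.70 ± 0.22), Arid1a (0.30 ± 0.10) and Phf10 (0.30 ± 0.10) also rose, and Dpf2 (-0.41 ± 0.10), Smarcd2 (-0.39 ± 0.10) and Smarce1 (-0.29 ± 0.10) fell, but no subunit gene passed the test of the difference between the times. These 6 calls and that of Bcl7c at 30 h are uncertain. They ended without DMSO 30 h replicate 1 for Dpf1 (adjusted p = 0.0570), Arid1a (0.19, adjusted p = 0.226), Smarcd2 (adjusted p = 0.0588) and Smarce1 (-0.20, adjusted p = 0.237), and without DMSO 30 h replicate 2 for Dpf1 (adjusted p = 0.111) and Phf10 (adjusted p = 0.128). Without BRM014 30 h replicate 1 they ended for Bcl7c (0.43, adjusted p = 0.0796), Phf10 (adjusted p = 0.119) and Smarce1 (adjusted p = 0.177), and without BRM014 30 h replicate 2 for Dpf1 (adjusted p = 0.120), Arid1a (adjusted p = 0.172), Dpf2 (adjusted p = 0.0515) and Smarce1 (adjusted p = 0.0604). Arid1a also lost its call without either BRM014 6 h library (adjusted p = 0.0550) and Smarce1 without any 1 of the 6 h libraries (adjusted p = 0.0543 to 0.0665). With only the 4 libraries of the comparison, Dpf1, Arid1a, Phf10 and Smarce1 did not pass (adjusted p = 0.0550, 0.0680, 0.0639 and 0.0998), with DESeq2 Dpf1 and Smarce1 did not (adjusted p = 0.0592 and 0.0509), and Smarce1 did not with library totals (adjusted p = 0.0625) or thinned counts (adjusted p = 0.0683). Scaling to ribosomal protein and oxidative phosphorylation genes (housekeeping scaling) gave the list a 30 h median of 0.09, with 6 members higher and none lower. Many oxidative phosphorylation genes fell at 30 h with TMM, and a falling reference raises all other genes. How much of the shift came from the oxidative phosphorylation genes was not computed, and their fall was itself measured with TMM. Of 17 tested genes of other remodelling complexes, 2 fell at 6 h (list adjusted p = 0.478), and 2 rose and 4 fell at 30 h (adjusted p = 0.873).

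After 6 h of BRM014, the 6 largest falls among the genes of the rule (mean log2 CPM of at least 2 over all 8 libraries) were in Krt6a, Il18rap, Il1rn, Ccl7, Cldn2 and Abi3. The keratin gene Krt6a (Entrez 16687) changed by -4.99 ± 0.37 (adjusted p = 1.12e-06), from 39.0 to 1.25 CPM. The tight junction gene Cldn2 (Entrez 12738) changed by -4.26 ± 0.15 (adjusted p = 1.75e-09), from 632 to 33.0 CPM. The interleukin receptor component Il18rap (Entrez 16174; -4.57 ± 0.18), the interleukin-1 antagonist Il1rn (Entrez 16181; -4.47 ± 0.30), the chemokine Ccl7 (Entrez 20306; -4.36 ± 0.33) and the actin regulator Abi3 (Entrez 66610; -4.04 ± 0.36) also fell. The largest rises started from low counts. Csdc2, which encodes an RNA-binding cold shock domain protein (Entrez 105859), changed by 4.44 ± 0.34 (adjusted p = 1.32e-06), from 4 and 6 counts in DMSO to 96 and 151. The interferon-inducible chemokine Cxcl10 (Entrez 15945) changed by 4.03 ± 0.63 (adjusted p = 0.000414), from 2 and 5 counts to 32 and 101. The secreted peptide precursor Vgf (Entrez 381677) changed by 3.83 ± 0.47, from 14 and 17 counts to 114 and 395. The protease gene Prss36 (2.12 ± 0.24), Txndc16 (2.07 ± 0.29) and the cytokine signalling suppressor Socs1 (2.07 ± 0.25) followed.

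The mesenchymal list and the NF-kB and inflammatory list passed as lower at 6 h at the preset correlation, but not with an estimated one. Of 15 tested mesenchymal genes, 9 fell, 1 rose and 5 did not pass (10 lower and 1 higher adjusted over the list alone). The falls included Sparc (-1.27 ± 0.11), the membrane protease gene Mmp14 (-1.07 ± 0.11) and S100a4 (-0.93 ± 0.10), and the riser, named after its value was seen, was Zeb1 (0.41 ± 0.12). The Zeb1 call ended without any 1 of the 6 h libraries (0.36 to 0.46, adjusted p = 0.0559 to 0.123) and with housekeeping scaling (adjusted p = 0.0520). The list passed with a median of -0.91 (adjusted p = 2.40e-05), and lost its call with adjusted p = 0.307 with an estimated correlation. Of 21 NF-kB and inflammatory genes, 11 fell, 4 rose and 6 did not pass (11 and 5 adjusted over the list alone), and the list passed with a median of -0.70 (adjusted p = 7.11e-05; adjusted p = 0.307 with an estimated correlation). The chemokines Ccl2 (-3.53 ± 0.18, 293 to 25.3 CPM), Cxcl5 (-1.91 ± 0.13) and Ccl7 were among the falls. The 4 risers, named after their values were seen, were the pathway components Relb (0.65 ± 0.15), Nfkbia (0.51 ± 0.12) and Nfkb1 (0.51 ± 0.10) and the chemokine Cxcl1 (0.61 ± 0.15). Of these only Nfkb1 kept its call with any library left out. Without DMSO 6 h replicate 2 Cxcl1 was 0.39 (adjusted p = 0.105) and Nfkbia 0.47 (adjusted p = 0.0725), and without BRM014 6 h replicate 2 Nfkbia was 0.34 (adjusted p = 0.134), Relb 0.56 (adjusted p = 0.0662) and Cxcl1 0.61 (adjusted p = 0.0615).

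Of 22 basement membrane and integrin genes, 11 fell, 2 rose and 9 did not pass at 6 h (13 and 2 adjusted over the list alone). Itga2 (-1.48 ± 0.12), Lamb3 (-1.06 ± 0.09) and Itgb6 (-2.28 ± 0.23) were among the falls, and the list passed with a median of -0.35 (adjusted p = 0.000423; adjusted p = 0.334 with an estimated correlation). Among 6 basal and myoepithelial genes 5 fell and 1 did not pass (5 adjusted over the list alone), with Lamb3 and Itgb4 (-0.84 ± 0.10) as examples. That list had a median of -0.89 (adjusted p = 0.00022; adjusted p = 0.307 with an estimated correlation). Of 16 epithelial junction and identity genes, 6 fell and 10 did not pass (7 adjusted over the list alone), including the desmosomal genes Pkp3 (-3.91 ± 0.42) and Jup (-0.87 ± 0.11) and the keratin gene Krt19 (-1.08 ± 0.14). Its median was -0.13 (adjusted p = 0.0234; adjusted p = 0.586 with an estimated correlation), and this call is uncertain. The median was -0.05 without BRM014 6 h replicate 1 (adjusted p = 0.0745) and -0.13 without DMSO 6 h replicate 2 (adjusted p = 0.103), where the call ended, as it did with fry (adjusted p = 0.0640). It was -0.25 without DMSO 6 h replicate 1, -0.20 without BRM014 6 h replicate 2 and -0.05 with library totals, where the list passed. Of 7 luminal and secretory genes, 3 fell, 1 rose and 3 did not pass (3 and 1 adjusted over the list alone). The falls were Muc1 (-2.04 ± 0.14), Xdh (-3.23 ± 0.30) and Areg (-1.26 ± 0.21), and the median was -0.89 (adjusted p = 0.0143; adjusted p = 0.307 with an estimated correlation; -0.40 without BRM014 6 h replicate 2).

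Of 12 Wnt pathway genes, 6 fell and 6 did not pass at 6 h (7 adjusted over the list alone), with Wnt7a at -3.87 ± 0.27, the receptor gene Fzd7 at -1.08 ± 0.14 and Ccnd1 at -0.41 ± 0.09 (-0.34, adjusted p = 0.112 without BRM014 6 h replicate 2). The list median was -0.65 (adjusted p = 0.0085; adjusted p = 0.371 with an estimated correlation; -0.39 without DMSO 6 h replicate 2 and -0.43 without BRM014 6 h replicate 2). Of 30 G1/S and DNA replication genes, 10 fell and 20 did not pass (11 lower and 1 higher adjusted over the list alone), with a median of -0.23 (adjusted p = 0.0314; adjusted p = 0.586 with an estimated correlation). The call ended without DMSO 6 h replicate 1 (-0.22, adjusted p = 0.0568), without BRM014 6 h replicate 2 (-0.17, adjusted p = 0.110) and with library totals (-0.15, adjusted p = 0.0514). Cdc6 (-0.70 ± 0.10) and Rrm2 (-0.76 ± 0.10), named after their values were seen, were among the falls. Of 23 glycolysis and hypoxia genes, 8 fell, 3 rose and 12 did not pass (10 and 3 adjusted over the list alone), with a median of -0.19 (adjusted p = 0.0436; adjusted p = 0.481 with an estimated correlation; -0.11 with library totals). The call ended without DMSO 6 h replicate 1 (-0.14, adjusted p = 0.0842), BRM014 6 h replicate 1 (-0.21, adjusted p = 0.0719), BRM014 6 h replicate 2 (-0.21, adjusted p = 0.0579) or BRM014 30 h replicate 1 (-0.16, adjusted p = 0.0534). Ndrg1 (-1.76 ± 0.16) and P4ha2 (-1.59 ± 0.15) fell and Pfkfb3 (1.30 ± 0.13) rose, also named after their values were seen. Cholesterol synthesis was the 1 list that passed upward at 6 h, with 5 of 24 members higher, 2 lower and 17 not passing (5 and 2 adjusted over the list alone). Its median was 0.28 (adjusted p = 0.0209; adjusted p = 0.718 with an estimated correlation; adjusted p = 0.381 with fry), with Dhcr7 (1.05 ± 0.14) and Hmgcs1 (1.16 ± 0.30, adjusted p = 0.012) among the higher members. Hmgcs1 lost its call without DMSO 6 h replicate 1 (1.00, adjusted p = 0.109) and without BRM014 6 h replicate 2 (0.86, adjusted p = 0.143).

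Several lists moved in both directions at 6 h and did not pass as groups. AP-1 and immediate early genes had 7 members higher and 5 lower among 27 (adjusted p = 0.296), with Egr1 (1.59 ± 0.26) and Atf3 (1.02 ± 0.16) higher and Junb (-1.06 ± 0.18) and Ier5 (-1.53 ± 0.16) lower. TGF-beta response genes had 3 higher and 7 lower among 20 (adjusted p = 0.273), including Id2 (-0.70 ± 0.12) among the lower. Unfolded protein and amino acid stress genes had 5 higher and 9 lower among 22 (adjusted p = 0.119), with Chac1 higher (1.80 ± 0.22) and Nupr1 (-3.85 ± 0.20) and the cystine transporter gene Slc7a11 (-2.89 ± 0.28) lower. These genes were named after their values were seen. YAP/TAZ-TEAD targets had 5 higher and 8 lower among 22 (adjusted p = 0.496), and their median of -0.01 became 0.07 with library totals and 0.02 with housekeeping scaling. The interferon response list had 3 higher and 2 lower among 23 (adjusted p = 0.356), p53 targets 5 higher and 4 lower among 24 (adjusted p = 0.212), and G2/M genes 4 lower among 28 (adjusted p = 0.122). Notch pathway genes had 2 lower among 12 (adjusted p = 0.0508), replication-dependent histone genes 4 lower among 9 (adjusted p = 0.0617) and Hox genes 2 higher among 7 (adjusted p = 0.328). None of 32 ribosomal protein genes (adjusted p = 0.679) or 25 oxidative phosphorylation genes (adjusted p = 0.411) passed at 6 h.

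In total, 1106 genes rose and 1709 fell at 6 h, so 60.7% of the changed genes were lower. At a fold of at least 2, 205 rose and 659 fell (76.3% lower). Scaling by library totals alone gave 1691 higher and 1391 lower genes (45.1% lower), with 69.1% lower at a fold of at least 2. The main counts of higher and lower genes were both smaller when any 1 of the 6 h libraries was left out, which leaves less power.

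**Figure D2:**
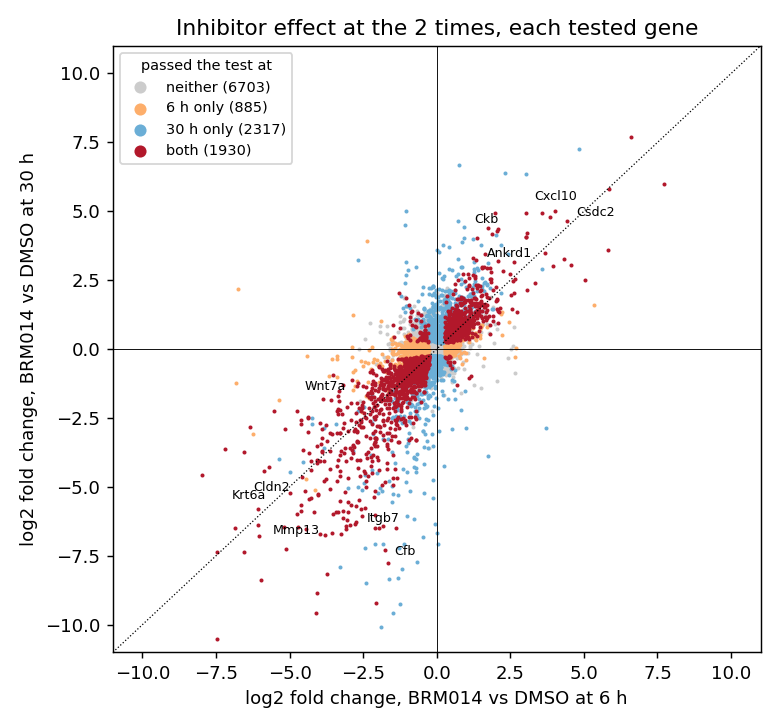
Log2 fold change of each of the 11835 tested genes at 30 h (vertical axis) against 6 h (horizontal axis), coloured by the times at which the gene passed the test; the dotted line marks equal effects. The effects at the 2 times correlated with r = 0.71, and Cfb and Itgb7 lay far below the dotted line.

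After 30 h of BRM014, the 6 largest falls among the genes of the rule were in Cfb, Ranbp3l, Mmp13, Pilra, Krt14 and Itgb7. Complement factor B, Cfb (Entrez 14962), changed by -7.29 ± 0.31 (adjusted p = 3.07e-09), from 35.5 to 0.211 CPM. The integrin gene Itgb7 (Entrez 16421) changed by -6.27 ± 0.23 (adjusted p = 1.01e-09), from 161 to 2.23 CPM, and the collagenase gene Mmp13 (Entrez 17386) by -6.70 ± 0.32. Ranbp3l (Entrez 223332, -7.07 ± 0.71) and the receptor gene Pilra (Entrez 231805, -6.37 ± 0.27) also fell. The replicates differed for Ranbp3l, with 302 and 1007 counts in DMSO and 1 and 10 in BRM014. The basal keratin gene Krt14 (Entrez 16664) fell (-6.36 ± 0.76, adjusted p = 2.71e-05) to 3 counts over the 2 BRM014 libraries against 218 in DMSO, a ratio of 87.0 with a 95% interval of 29.4 to 425 that covers counting error only. The largest rises were in Cxcl10 (5.03 ± 0.37, 1.08 to 36.1 CPM), Vgf (4.79 ± 0.54), Csdc2 (4.65 ± 0.25), the creatine kinase gene Ckb (Entrez 12709; 4.16 ± 0.30), the interferon-inducible GTPase gene Gbp2 (Entrez 14469; 4.01 ± 0.29) and Rnd1 (Entrez 223881; 3.30 ± 0.20).

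Cell cycle genes fell broadly at 30 h. Of 30 G1/S and DNA replication genes, 22 fell, 1 rose and 7 did not pass (23 and 1 adjusted over the list alone), including Cdc6 (-1.08 ± 0.10), the ribonucleotide reductase gene Rrm2 (-0.98 ± 0.11) and the primase gene Prim1 (-0.79 ± 0.10). The list median was -0.51 (adjusted p = 1.08e-05; adjusted p = 0.307 with an estimated correlation). Of 28 G2/M and mitosis genes, 23 fell and 5 did not pass (24 adjusted over the list alone), including Bub1b (-0.71 ± 0.09), Cdc25c (-0.75 ± 0.12) and Ccna2 (-0.58 ± 0.09). Their median was -0.41 (adjusted p = 7.11e-05; adjusted p = 0.307 with an estimated correlation). Housekeeping scaling left 17 and 12 members lower in these lists.

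The glycolysis and hypoxia list and the oxidative phosphorylation list also passed as lower at 30 h at the preset correlation, but not with an estimated one. Of 23 glycolysis and hypoxia genes, 14 fell, 2 rose and 7 did not pass (15 and 3 adjusted over the list alone), with a median of -0.45 (adjusted p = 0.00259; adjusted p = 0.307 with an estimated correlation). Ldha (-1.28 ± 0.09) and P4ha2 (-1.50 ± 0.15) fell, whereas Pfkfb3, whose product promotes glycolysis, rose (1.85 ± 0.13). Of 25 oxidative phosphorylation genes, 16 fell and 9 did not pass (19 adjusted over the list alone), with Sdha (-0.45 ± 0.09), Cox5a (-0.45 ± 0.09) and Atp5b (-0.38 ± 0.08) as examples. The list median was -0.29 (adjusted p = 0.0089; adjusted p = 0.586 with an estimated correlation), and housekeeping scaling, which uses this list itself, left 3 members lower. Among 24 cholesterol synthesis genes 12 fell, 2 rose and 10 did not pass, and the list did not pass (median -0.46, adjusted p = 0.0628).

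Interferon response genes rose at 30 h, with 15 of 23 higher, 2 lower and 6 not passing (15 and 2 adjusted over the list alone). Gbp2, Cxcl10 and the transcription factor gene Irf1 (1.77 ± 0.15) were among the risers, and the list median was 0.87 (adjusted p = 2.40e-05; adjusted p = 0.307 with an estimated correlation). The 2 members that fell, named after their values were seen, were Mx1 (-5.97 ± 0.57; 2 counts over the BRM014 libraries against 119 in DMSO, a ratio of 71.2 with a 95% interval, for counting error only, of 19.3 to 595) and Irgm1 (-1.08 ± 0.13). Of 22 YAP/TAZ-TEAD targets, 13 rose, 4 fell and 5 did not pass (13 and 5 adjusted over the list alone), with Ankrd1 (3.22 ± 0.13) and F3, which encodes tissue factor (2.35 ± 0.14), higher and Foxf2 (-1.79 ± 0.13) lower. Their median was 0.45 (adjusted p = 0.000367; adjusted p = 0.387 with an estimated correlation). Of 24 p53 targets, 11 rose, 3 fell and 10 did not pass (13 and 3 adjusted over the list alone; median 0.46, adjusted p = 0.0194; adjusted p = 0.674 with an estimated correlation and 0.154 with fry). Without BRM014 30 h replicate 1 the median was 0.29 and the call ended (adjusted p = 0.169). Named after their values were seen, the apoptosis gene Bbc3 rose (1.76 ± 0.18), but Cdkn1a (-0.76 ± 0.23), which encodes the cell cycle inhibitor p21, and Gdf15 (-3.35 ± 0.24) fell. The Cdkn1a value was -0.50 (adjusted p = 0.206) without BRM014 30 h replicate 2 and -0.59 (adjusted p = 0.0911) without DMSO 30 h replicate 1, and its call also ended with DESeq2 (adjusted p = 0.124) and housekeeping scaling (adjusted p = 0.0625), so that this fall is uncertain.

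Basement membrane and integrin genes, which fell at 6 h, rose as a group at 30 h, with 12 of 22 higher, 5 lower and 5 not passing (12 and 6 adjusted over the list alone). The laminin gene Lamb1 (1.76 ± 0.13) and the collagen IV genes Col4a1 (1.00 ± 0.09) and Col4a2 (1.08 ± 0.10) rose, and the list median was 0.41 (adjusted p = 0.0089; adjusted p = 0.481 with an estimated correlation). Of 15 mesenchymal genes, 7 fell, 3 rose and 5 did not pass (8 and 3 adjusted over the list alone; median -0.41, adjusted p = 0.0194; adjusted p = 0.371 with an estimated correlation). S100a4 (-3.30 ± 0.11) and Sparc (-1.28 ± 0.11) fell, whereas Cdh2 (1.05 ± 0.13) and Fn1 (0.80 ± 0.10) rose, all named after their values were seen. Of 12 Notch pathway genes, 7 fell, 1 rose and 4 did not pass (8 and 1 adjusted over the list alone; median -0.61, adjusted p = 0.0382; adjusted p = 0.307 with an estimated correlation, 0.0513 without DMSO 30 h replicate 1 and 0.0647 without BRM014 30 h replicate 1), including Hes1 (-1.36 ± 0.16) and Jag1 (-1.15 ± 0.13), named in the same way. Of 7 luminal genes, Muc1 (-3.90 ± 0.16), Xdh (-2.35 ± 0.22) and Areg (-0.62 ± 0.21, adjusted p = 0.0379) fell and 4 did not pass (3 lower adjusted over the list alone). The Areg value was -0.26 (adjusted p = 0.359) without DMSO 30 h replicate 1 and -0.45 (adjusted p = 0.261) without BRM014 30 h replicate 2. Its call also ended without either BRM014 6 h library (adjusted p = 0.0542 and 0.0543), with DESeq2 (adjusted p = 0.166) and housekeeping scaling (adjusted p = 0.0943). The luminal list passed (adjusted p = 0.0114; adjusted p = 0.307 with an estimated correlation) with a mean of -0.80, but its median of -0.03 became 0.01 with library totals and 0.11 with housekeeping scaling. It was -0.22 without DMSO 30 h replicate 1, 0.04 without DMSO 30 h replicate 2, 0.03 without BRM014 30 h replicate 1 and -0.08 without BRM014 30 h replicate 2, so that it has no clear direction.

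**Figure D3:**
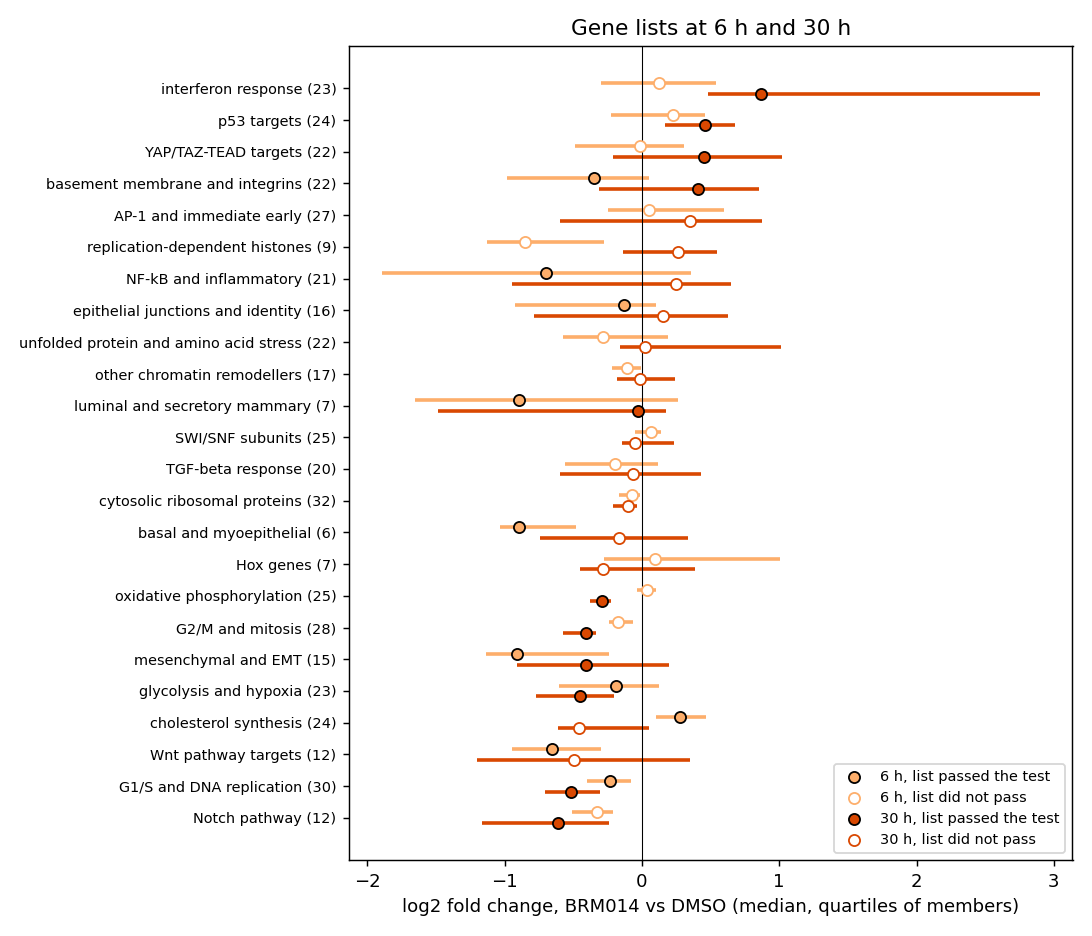
Median (points) and quartiles (bars) of the log2 fold changes of the tested members of each gene list, BRM014 against DMSO, at 6 h and 30 h; the number of tested members is in brackets and filled points mark lists that passed the test. The basement membrane and integrin list had a median of -0.35 at 6 h and 0.41 at 30 h.

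Other lists held changes in both directions at 30 h and did not pass. AP-1 and immediate early genes had 14 members higher and 8 lower among 27 (adjusted p = 0.198), with Atf3 (2.17 ± 0.16) and Nr4a1 (2.13 ± 0.23) higher and Fos (-2.12 ± 0.21) and Junb (-0.72 ± 0.17) lower. The Junb value was -0.38 (adjusted p = 0.0752) without DMSO 30 h replicate 1 and -0.64 (adjusted p = 0.0577) without BRM014 30 h replicate 1. TGF-beta response genes had 5 higher and 5 lower among 20 (adjusted p = 0.533), with Id1 (-1.24 ± 0.10), Id2 (-2.52 ± 0.13) and Id3 (-0.55 ± 0.15) among the lower. The Id3 call ended without BRM014 30 h replicate 1 (-0.51, adjusted p = 0.0692) and with housekeeping scaling (-0.41, adjusted p = 0.118). Unfolded protein and amino acid stress genes had 8 higher and 3 lower among 22 (adjusted p = 0.119), with Chac1 (2.95 ± 0.22), Ddit3 (1.58 ± 0.16) and Trib3 (1.40 ± 0.14) higher and Nupr1 (-4.78 ± 0.19) lower. Epithelial junction and identity genes had 3 higher, namely Krt8 (0.67 ± 0.10), Krt18 (0.79 ± 0.11) and Cdh1 (0.67 ± 0.13), and 6 lower among 16 (adjusted p = 0.679), and their median (0.15) and mean (-0.39) differed in sign. NF-kB and inflammatory genes had 8 higher and 7 lower among 21 (adjusted p = 0.666), with a median of 0.24 and a mean of -0.18. Wnt pathway genes had 3 higher and 5 lower among 12 (adjusted p = 0.26), and basal genes 2 higher and 3 lower among 6 (adjusted p = 0.328). Replication-dependent histone genes had 2 higher and 1 lower among 9 (adjusted p = 0.639), ribosomal protein genes 2 lower among 32 (adjusted p = 0.398), and none of 7 Hox genes passed (adjusted p = 0.798). The genes of this paragraph were named after their values were seen.

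In total, 1990 genes rose and 2258 fell at 30 h (53.2% lower), with 551 and 779 at a fold of at least 2 (58.6% lower). Housekeeping scaling shifted the median of all genes at 30 h from -0.005 to 0.14, with 2755 higher and 1349 lower genes (32.9% lower, and 48.4% at a fold of at least 2). Its reference includes the oxidative phosphorylation genes, many of which fell at 30 h with TMM. A falling reference raises all other genes, but how much of the shift came from the oxidative phosphorylation genes was not computed. Their fall was itself measured with TMM. RLE factors gave 51.9% and library totals 47.5% lower, so the balance of directions at 30 h rests on the scaling.

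The 2 times shared much of their response. Of the 1106 genes higher at 6 h, 715 (64.6%) were also higher at 30 h, where independent lists would share 186 (odds ratio 13.6, 95% interval 11.8 to 15.6). Of the 1709 lower at 6 h, 1148 (67.2%) were also lower at 30 h against 326 for independent lists (odds ratio 16.6, 95% interval 14.7 to 18.7). The shared genes included Csdc2, Cxcl10 and Vgf among the risers and Cldn2, Mmp13, Itgb7 and Muc1 among the falls. Only 16 genes that rose and 52 that fell at 6 h passed in the opposite direction at 30 h, and 375 and 509 did not pass at 30 h. The shared higher genes numbered 455 without DMSO 6 h replicate 1, 471 without DMSO 6 h replicate 2 and 374 without BRM014 6 h replicate 2, and the shared lower genes 719 without the last of these. Across all tested genes the effects correlated with r = 0.71 and had the same sign in 71.9%.

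The inhibitor effect itself differed between 30 h and 6 h for 766 genes, 460 more positive and 306 more negative at 30 h. Among the more negative were Cfb (-5.52 ± 0.48, adjusted p = 3.92e-05), Itgb7 (-3.53 ± 0.28), the troponin gene Tnnt2 (Entrez 21956; -3.52 ± 0.50) and Mmp13 (-3.46 ± 0.45). Among the more positive were the immune receptor gene Siglecg (Entrez 243958; 3.30 ± 0.60, adjusted p = 0.00491), Tnfaip2 (Entrez 21928; 3.14 ± 0.39), Gbp2 (2.78 ± 0.66, adjusted p = 0.0237) and the metalloprotease gene Adam8 (Entrez 11501; 2.71 ± 0.28). The Gbp2 call ended without DMSO 6 h replicate 1 (2.43, adjusted p = 0.225), DMSO 6 h replicate 2 (adjusted p = 0.0581), BRM014 6 h replicate 1 (adjusted p = 0.0687), BRM014 6 h replicate 2 (adjusted p = 0.0738) or BRM014 30 h replicate 2 (adjusted p = 0.0687). Of 22 basement membrane and integrin genes 13 had a more positive effect at 30 h and none a more negative one, including Itga2 (2.36 ± 0.17), Lamb1 (1.72 ± 0.17) and Itga3 (1.15 ± 0.16; 14 adjusted over the list alone; list adjusted p = 0.115 with an estimated correlation).

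YAP/TAZ-TEAD targets had 12 of 22 members with a more positive effect at 30 h and none with a more negative one (13 and 1 adjusted over the list alone), including Ankrd1 (1.88 ± 0.17) and F3 (1.72 ± 0.20). The list had adjusted p = 0.193 with an estimated correlation. Between the times Ankrd1 fell in DMSO from 585 to 178 CPM, with 1480 and 1654 CPM in BRM014. F3 fell in DMSO from 147.5 to 67.9 CPM and rose in BRM014 from 229 to 346 CPM. For this list, a decline in DMSO and a rise in BRM014 were not weighed against each other. Inflammatory genes had 7 of 21 more positive and none more negative (14 and 0 adjusted over the list alone), including Ccl2 (2.58 ± 0.23) and Csf1 (0.97 ± 0.14), and had adjusted p = 0.115 with an estimated correlation. Outside these lists, the effect on Slc7a11 (2.60 ± 0.36) was more positive and that on Id2 (-1.82 ± 0.17) more negative at 30 h. The list members and these 2 genes were named, and the list tests of the difference added, after the data were seen. The count of 766 fell to 353 without DMSO 6 h replicate 1, 386 without BRM014 6 h replicate 1, 329 without BRM014 6 h replicate 2 and 411 without BRM014 30 h replicate 2, and rose to 1309 without a filter on low counts. Housekeeping scaling, which shifted the median difference of all genes from 0.008 to 0.13, changed the share of more negative genes from 39.9% to 19.1% (495 and 117 genes). Its reference includes the oxidative phosphorylation genes, whose own median difference was -0.32 with TMM. How much of the shift came from them was not computed.

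**Figure D4:**
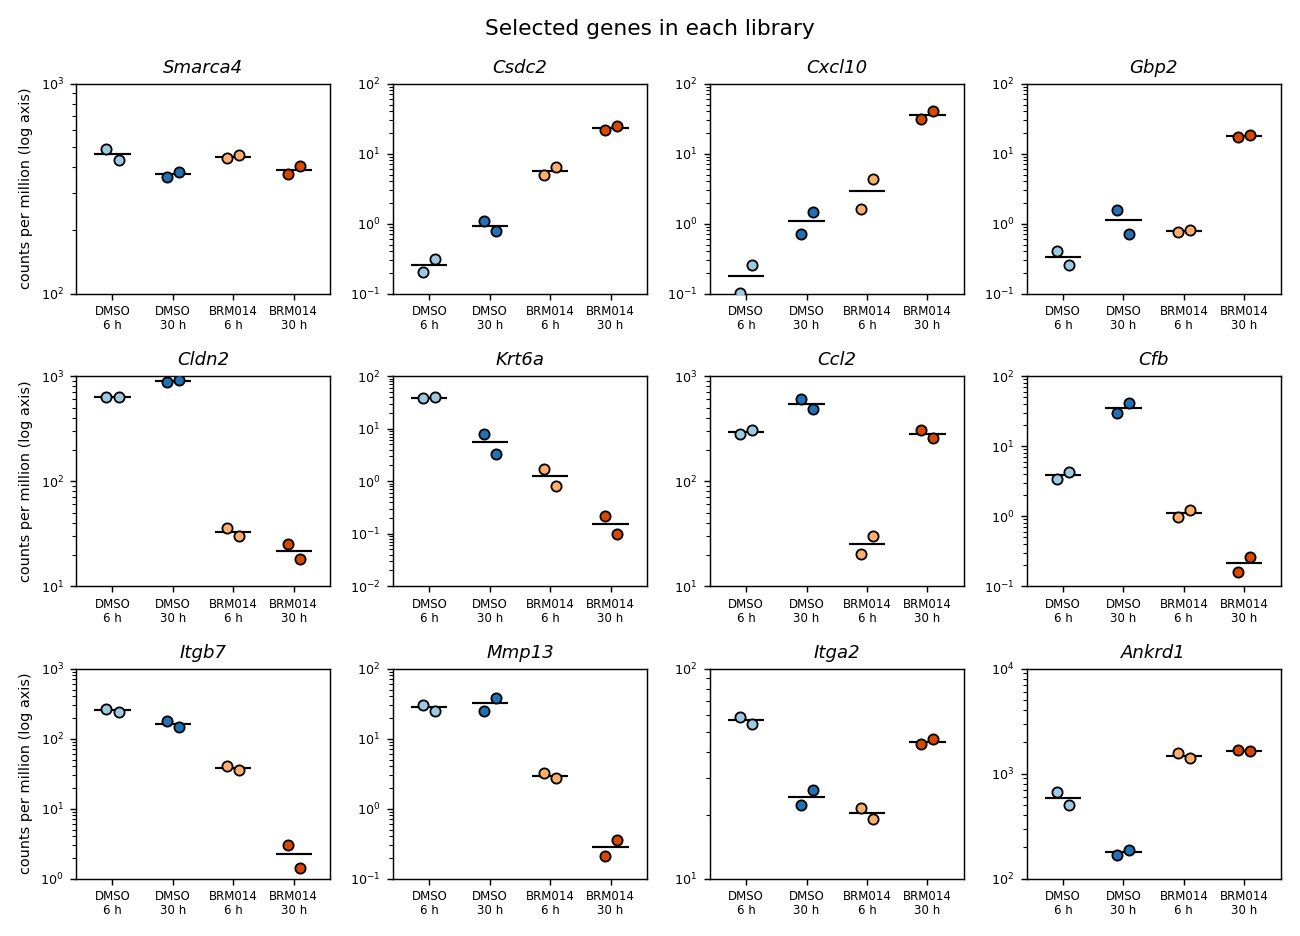
CPM (log axes) of 12 genes in each of the 8 libraries (points) with the mean of each group (lines). Cldn2 fell from 632 to 33.0 CPM at 6 h, while Smarca4 stayed between 369 and 460 in all 4 group means.

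Vehicle-treated cells also changed between 6 h and 30 h, with 2133 genes higher and 2034 lower at 30 h. Ranbp3l (5.61 ± 0.63), the transcript AW112010 (Entrez 107350; 3.78 ± 0.52), the lipopolysaccharide-binding protein gene Lbp (Entrez 16803; 3.40 ± 0.18) and the epithelial transcription factor gene Ehf (Entrez 13661; 3.31 ± 0.38) rose. Lce1g (Entrez 66195; -4.25 ± 0.43), Prl2c3 (Entrez 18812; -4.00 ± 0.34), Siglecg (-3.69 ± 0.45) and S100a7a (Entrez 381493; -3.05 ± 0.32) fell. Outside the rule and named after their values were seen, complement C3 (4.01 ± 0.23), Ccl20 (3.13 ± 0.28) and the hypoxia genes Pdk1 (2.49 ± 0.14) and Bnip3 (2.47 ± 0.19) rose, as did Smarca2 (1.06 ± 0.23). Ankrd1 (-1.72 ± 0.13), Cdc6 (-0.67 ± 0.10) and Mcm10 (-0.75 ± 0.11) fell. Scaling by library totals gave 2754 higher and 1424 lower genes (34.1% lower against 48.8%), and without DMSO 6 h replicate 1 the total was 2363 genes in place of 4167.

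Inflammatory genes were higher at 30 h than at 6 h in vehicle (15 of 21 higher, 3 lower; 15 and 4 adjusted over the list alone), as were interferon response genes (13 of 23 higher, 1 lower; 14 and 1) and glycolysis and hypoxia genes (13 of 23 higher, 3 lower; 13 and 4). The oxidative phosphorylation (13 of 25 higher, and 16 adjusted over the list alone) and cholesterol synthesis lists (7 of 24 higher, and 7) also passed as higher. The lists of YAP/TAZ-TEAD targets (13 of 22 lower, 2 higher, and 14 and 2 adjusted over the list alone) and basement membrane and integrin genes (12 of 22 lower, 2 higher, and 15 and 2) passed as lower. So did those of G1/S (21 of 30 lower, and 22), G2/M (14 of 28 lower, and 15) and ribosomal protein genes (6 of 32 lower, and 6). Most cholesterol synthesis and ribosomal protein genes did not pass singly, where 35.2% of all genes passed. These list tests were added after the data were seen. All 10 lists lost their call, with adjusted p = 0.272 to 0.666 with an estimated correlation.

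In BRM014, 2318 genes were higher and 1999 lower at 30 h than at 6 h. Inflammatory genes (16 of 21 higher, none lower; 18 adjusted over the list alone) had a mean of 1.83 and kept their call with an estimated correlation (adjusted p = 0.0243). Interferon response genes (17 of 23 higher, none lower; 18 adjusted over the list alone; mean 2.47) lost it, with adjusted p = 0.0645 with an estimated correlation. The same held for G1/S genes (27 of 30 lower, 1 higher; 28 and 1) and G2/M genes (26 of 28 lower; 27). The comparison and its list tests were added after the data were seen. The total of 4317 genes was 2248 without BRM014 6 h replicate 1 and 2840 without BRM014 6 h replicate 2, and the share of lower genes was 26.8% with housekeeping scaling in place of 46.3%. The time changes in DMSO and in BRM014 correlated with r = 0.50.

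Some named genes are less certain in identity. In the reference annotation the spans of Abi3, Itgb4, Ccnd1, Pilra, Ccna2, Phf10, Ddit3, Plin4, Syn1, Lipe and of the neighbours Col4a1 and Col4a2 overlap another tested gene, and the strand setting of the counting was not given in the sources used here. Prl2c3 and Krt6a belong to families with near-identical copies, whose reads of 50 bases can be placed on more than 1 copy.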

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

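The tests of the basement membrane and integrin list and the list tests of the difference between the times were chosen after their results were seen. The other tests here were written down before their values were known, though for patterns noticed in the same data.

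The test of the difference between the inhibitor effects at 30 h and 6 h passed for 766 genes. By name, the effect at 30 h exceeded that at 6 h for Siglecg (3.30), Tnfaip2 (3.14), Gbp2 (2.78; its call ended in 5 of the 8 fits with 1 library left out, adjusted p = 0.0581 to 0.225) and Adam8 (2.71), and lay below it for Cfb (-5.52), Itgb7 (-3.53), Tnnt2 (-3.52) and Mmp13 (-3.46). Siglecg fell in DMSO between the times, from 9.59 to 0.773 CPM, and less in BRM014, from 4.01 to 3.08 CPM. Cfb rose in DMSO from 3.81 to 35.5 CPM and was lower at 30 h in BRM014, from 1.11 to 0.211 CPM (19 and 29 counts, then 3 and 8).

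Of 24 gene lists, 14 passed the test of the difference at the preset correlation. Their median differences were 0.77 for basement membrane and integrin genes, 0.54 for YAP/TAZ-TEAD targets, 0.72 for NF-kB and inflammatory genes, 0.98 for the interferon response, 1.16 for replication-dependent histones, 0.54 for unfolded protein and amino acid stress, 0.53 for basal, 0.38 for epithelial junction and 0.37 for p53 target genes. They were -0.61 for cholesterol synthesis, -0.32 for oxidative phosphorylation, -0.31 for G1/S, -0.22 for glycolysis and hypoxia and -0.21 for G2/M genes. For the basal list the mean (-0.12) had the opposite sign. All 14 lost their call with an estimated correlation (adjusted p = 0.115 to 0.599).

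The basement membrane and integrin list had a median of -0.35 at 6 h and 0.41 at 30 h, with members called in both directions at each time. The tables argue against the choice of scaling as the cause, since the lowest median difference under RLE factors, library totals and housekeeping scaling was 0.72. These scalings put the median difference of all genes at 0.005, -0.04 and 0.13, and a shift that all of them share was not tested. The tables also argue against a single library, since the lowest median difference with 1 library left out was 0.68. The standard error of the median was 0.18 over 22 members taken as independent, and it does not measure the spread between libraries. A decline in vehicle alone is argued against as the whole cause, since the median change was -0.40 in DMSO but 0.50 in BRM014. For BRM014 the interval over members was 0.04 to 0.63, and the median was 0.29 without BRM014 30 h replicate 2. In BRM014, 14 of 22 members passed as higher and 4 as lower (17 positive, exact sign test p = 0.0169, taking members as independent). An effect of the inhibitor that changes with time may explain the pattern, as a hypothesis found and tested on the same data. It was not tested further, and the list lost its call with an estimated correlation.

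More genes fell than rose at least 2-fold at 6 h. Against scaling of the libraries, the share of lower genes was at least 69.1% (95% interval 65.8% to 72.2%) under the other scalings. Against noise of weakly expressed genes, it was 83.9% (71.7% to 92.4%) and 91.4% (82.3% to 96.8%) in the 2 quintiles of highest expression. Against a single library, it was at least 72.4% (69.1% to 75.5%) with 1 library left out. The intervals of these shares take genes as independent and do not measure the spread between libraries. A loss of expression from inhibiting the ATPases may account for the excess of falls, as a hypothesis. A global change of RNA per cell stays open because the labels name no added standard.

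In the chromosome order of the tested genes, genes that fell at 30 h were next to each other more often than expression-matched random placement gave (564 adjacent pairs against 430, range 398 to 464). Untested genes between the members of a pair were skipped and the distance was not limited, so a pair need not be direct neighbours on the chromosome. Against chance placement, the permutation p was 0.0001, the smallest that 10000 permutations can give. Against reads shared between related genes, it was 0.0001 without pairs sharing the first 3 letters of their symbols (504 against 413), and against overlapping gene models 0.0001 without overlapping pairs (521 against 390). Genes that rose at 30 h were also paired more often (461 against 333), so the pairing was not particular to falls. Neighbours that respond together may be a candidate explanation, as a hypothesis, while transcripts running from 1 gene into the next were not tested.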

How the results depend on the processing

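The alternatives for the counts of genes per comparison were chosen before the data were examined. Most of those for the genes higher or lower at both times, and the names of some genes, were chosen after the data were seen. With 1 library left out, its group's lone library was assumed to vary like the other groups.

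RLE factors, limma-voom and no filter ended no named gene's call, nor did the stricter filter, under which 7 of 170 were not tested. RLE factors and the stricter filter ended no list's call. At a fold of at least 2 the counts were 205 higher and 659 lower genes at 6 h, 551 and 779 at 30 h, 358 for the difference between the effects, 843 for time in DMSO, and 143 higher and 440 lower at both times, fewer by construction. Library totals gave 1691 higher genes at 6 h, with the median of all genes moved from -0.01 to 0.07. Housekeeping scaling gave 1349 lower genes at 30 h, with that median moved from -0.005 to 0.14. Without a filter 1309 genes passed the test of the difference between the effects, with 15650 genes tested, and the cause was not tested.

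With 1 library left out, the counts ran from 479 to 1259 (6 h higher), 943 to 1885 (6 h lower), 329 to 925 (difference between the effects), 2363 to 4197 (time in DMSO), 374 to 691 (higher at both times) and 719 to 1097 (lower at both times). Fewer libraries leave less power, and the 30 h counts stayed within 1.5 times.

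Smarca4 at 6 h changed sign with library totals (0.0488) and, over the fits with 1 library left out, ran from -0.12 to 0.05, positive without DMSO 6 h replicate 1 (0.0478) and without BRM014 6 h replicate 1 (0.00698). Smarca2 at 6 h ran from -0.08 to 0.28, negative without DMSO 6 h replicate 2 (-0.00946) and without BRM014 6 h replicate 1 (-0.0834). Neither passed the test in any of these.

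Replicates share only a number in the labels, and the deviations of equal numbers correlated with 0.01 to 0.20 across pairs of groups. With the replicate block, 1237 genes passed the test of the difference between the effects in place of 766. The other comparisons also gained genes, with 3354 in place of 2815 at 6 h and 4873 in place of 4248 at 30 h. Time in DMSO gave 4851 in place of 4167, and time in BRM014 4894 in place of 4317. None of these other counts moved by over 1.5 times, and no named gene or list changed its call. An effect shared by libraries of equal number stays open.

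Of 170 named gene results, housekeeping scaling ended 8 calls, DESeq2 4, only the 4 libraries of the comparison 4 of 153, library totals 1 and thinning 1, with the direction unchanged. Leaving out 1 library ended between 3 and 11 calls each. Smarce1 at 30 h lost its call without any 1 of 7 of the 8 libraries (adjusted p = 0.0543 to 0.237), and the calls of Dpf1, Arid1a, Phf10, Dpf2, Smarcd2, Cdkn1a, Id3, Areg, Junb, Cd68, Bcl7c, Col5a1, Syn1 and Gap43 at 30 h, of Ccnd1, Hmgcs1, Nfkbia, Relb, Cxcl1 and Zeb1 at 6 h, and of Gbp2 for the difference each ended without at least 1 library.

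All 21 list calls ended with an estimated correlation. fry kept 18, not epithelial junctions and cholesterol synthesis at 6 h and p53 targets at 30 h. Library totals ended the G1/S call at 6 h (adjusted p = 0.0514). Without DMSO 6 h replicate 1 the G1/S (0.0568) and glycolysis (0.0842) calls at 6 h ended, without DMSO 6 h replicate 2 epithelial junctions (0.103), without BRM014 6 h replicate 1 epithelial junctions (0.0745) and glycolysis (0.0719), and without BRM014 6 h replicate 2 G1/S (0.11) and glycolysis (0.0579). Without DMSO 30 h replicate 1 the Notch call at 30 h ended (0.0513), and without BRM014 30 h replicate 1 the Notch (0.0647), p53 (0.169) and 6 h glycolysis (0.0534) calls.

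Thinning to the smallest library left each count within 1.5 times. In simulations at the full depth with 200 changed genes, a change of 1.5-fold was recovered in 22.4% of genes for the difference between the effects. That count can therefore miss small differences, but recovery with as many changed genes as in the data was not simulated.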

Other observations

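Genes listed beforehand as markers of other cell types were measured in these cultures, and those that passed at 30 h moved in different directions. Of 4 tested fibroblast markers 1 rose and 2 fell: the matrix gene Fbln2 rose (1.71 ± 0.10) after falling in DMSO between the times (-1.53 ± 0.10), while the collagen genes Col1a1 (-2.06 ± 0.49) and Col5a1 (-0.76 ± 0.24) fell. The Col5a1 value was -0.21 (adjusted p = 0.453) without DMSO 30 h replicate 1 and over 1.5 times larger without DMSO 30 h replicate 2. Its call also ended without BRM014 30 h replicate 1 (adjusted p = 0.0557), without BRM014 30 h replicate 2 (adjusted p = 0.176) and with housekeeping scaling (adjusted p = 0.0651). Of 4 tested neuronal markers, Tubb3 (4.42 ± 0.64; 3 counts over the DMSO libraries against 86, a ratio of 0.0418 with a 95% interval, for counting error only, of 0.00844 to 0.126), Celf4 (2.18 ± 0.37) and Syn1 (1.08 ± 0.32) rose, and Gap43 fell from 11 counts over the DMSO libraries to 0. The Syn1 call ended without DMSO 30 h replicate 2 (0.75, adjusted p = 0.145), BRM014 30 h replicate 1 (adjusted p = 0.0579) or BRM014 30 h replicate 2 (adjusted p = 0.0605), and that of Gap43 without DMSO 30 h replicate 1 (adjusted p = 0.0554) or BRM014 30 h replicate 2 (adjusted p = 0.0748). The endothelial gene Egfl7 rose (1.39 ± 0.24) and the macrophage gene Cd68 fell (-1.12 ± 0.29), but Cd68 was -0.74 (adjusted p = 0.0871) without DMSO 30 h replicate 1 and -1.03 (adjusted p = 0.0671) without BRM014 30 h replicate 2. Of 4 tested adipocyte markers, Plin4 (-4.02 ± 0.52) and Lipe (-0.80 ± 0.20) fell. These genes were named after their values were seen, and each list had fewer than 5 tested members.

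Summed over all 12 fibroblast markers in the table, most of it from Fbln2, the level was 1849 and 1752 CPM in DMSO at 6 h, 707 and 570 CPM in DMSO at 30 h, and 1983 and 2055 CPM in BRM014 at 30 h. All 14 neuronal markers summed to 4.02 and 2.28 CPM in DMSO at 30 h and to 9.79 and 9.39 CPM in BRM014 at 30 h. All 10 adipocyte markers summed to 132 and 121 CPM in DMSO at 30 h and to 135 and 145 CPM in BRM014 at 30 h, and all 13 leukocyte markers to between 2.94 and 8.37 CPM in every library.

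The share of genes that passed with a fold of at least 2 differed by expression, but part of this can be built in. The quintiles were set by the mean over the same 8 libraries, so a gene that falls far is itself moved to a lower quintile. The filter also keeps a gene with enough counts in only some libraries, so a weakly expressed gene can pass through the group where it is high. From the lowest to the highest quintile of mean expression it was 19.1%, 7.77%, 4.35%, 2.37% and 2.96% at 6 h, and 31.6%, 10.5%, 5.66%, 3.30% and 5.15% at 30 h.

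Among genes that fell at least 2-fold at 30 h, 135 pairs adjacent in the order of tested genes were found against 52.3 for expression-matched random placement, and 98 against 46.8 without pairs sharing the first 3 letters of their symbols (permutation p = 0.0001 for both, the smallest that 10000 permutations can give). These counts were added after the data were seen.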
